A study of Arabidopsis thaliana with 39 samples.

How the data were processed

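RNA sequencing libraries of Arabidopsis thaliana were compared in 13 groups of 3 libraries, 39 in all. Seedling set 1 held wild type Col0, fld and ld, seedling set 2 held Col0, ld, pol2a and ld pol2a, and seedling set 3 held Col0 and ld. The apex set held Col0, ld, pol2a and ld pol2a. Plants were grown for 7 days in 16 h of light per day, per the labels' protocols. Seedling RNA was extracted with Trizol and carried a spike-in, an external RNA added before library preparation; apex RNA came from 30 dissected shoot apices per sample, extracted with a column kit and without a spike-in. Libraries were made with the NEBNext Ultra II RNA kit, per the labels' protocols. Whether the counting used strand is not given in the sources used here, so overlapping genes on opposite strands were treated as uncertain. The columns named abo were matched to pol2a through the sample titles. The mutant alleles, the amount of spike-in and the organism it came from are not given in the sources used here.

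Per the submitters' processing notes, Trimmomatic 0.38, HISAT2, SAMtools 1.9, featureCounts, deepTools and DESeq2 were used with the TAIR10 build. The apex values are whole-number counts of reads per gene, deposited without normalisation. The seedling values are signal, gene counts that the authors divided by 1 size factor per library; the labels name a spike-in, and a factor taken from spike-in reads is how the values are read here, since the factors themselves were not analysed here. In each seedling library all values were whole multiples of 1 smallest value, taken as 1 read (100% within a tolerance of 0.1 reads). The whole counts so recovered are called reads and gave the depth. In sets 1 and 2 they are not raw reads, as the missing direction described below shows. In units of 1e6 reads, recovered totals were 10.4 to 14.4 in set 1, 13.2 to 35.0 in set 2 and 23.1 to 37.8 in set 3, and the apex libraries held 11.95 to 21.1. The apex table listed 33562 genes and each seedling table had 28775. Symbols were taken from the TAIR10.1 reference by locus identifier, which matched 32820 and 28009 of them. Positions are given in TAIR10.1; the authors' build is named TAIR10, and the tables carry no coordinates of their own.

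The tests and covariates, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Seedling values were tested within each set with limma 3.58.1 (R 4.3.3) on log2(signal + 1), with a mean-variance trend, for genes with a mean of at least 10 over the set. Fold changes are on that scale, which understates the change of low genes. All groups of a set shared 1 estimate of the spread. Apex counts were tested with the quasi-likelihood test of edgeR 4.0.16 (robust) after TMM scaling and filterByExpr, and apex levels are given in TMM-scaled CPM (counts per 1e6 reads). P-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. Since the spike-in scale moved the median of all genes, each seedling comparison was also fitted on a median-of-ratios scale, which sets that median shift to about 0; changes on that scale are called relative to the shift. Summed signals were compared by exact two-sided permutation tests, whose smallest p for 3 against 3 is 0.1. Deviations were not pooled across sets, which were scaled separately. The interaction was the effect of ld with pol2a minus the effect of ld without it.

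Named genes were LD, FLD, POL2A and FLC in every set. For each comparison against Col0 the 6 largest rises and 6 largest falls were added, among called genes with a symbol, a mean of at least 50 and no overlap between the libraries of the groups. The other contrasts took 4 each way, each list up to 4 members with the smallest p, and the genes called in 1 direction in every ld comparison the 10 with the largest mean change. On the spike-in scale few genes fell, so some falls were the largest available.

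The 19 lists covered the targets and the autonomous flowering pathway, floral repressors, floral promoters, floral organ identity, Polycomb components, the DNA damage response, DNA replication and S phase, mitosis, RNA polymerase II and elongation, housekeeping genes, photosynthesis, root markers, shoot meristem, abscisic acid and water stress, immunity, heat shock, the circadian clock, seed maturation and silenced loci. Of 255 members written, 2 were left out because the reference gave the identifier another symbol. Lists were tested with camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation, and with fry. Camera compares a list with the other genes, and fry asks whether the members move, on balance, one way. List p-values were adjusted over the lists of a comparison. A list of 12 trichome genes was written after the largest pol2a changes were seen, so it is given as counts without a list test.

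Before groups were averaged, replicates were compared by chi-square tests of reads over genes. In seedling set 1 the chi-square per degree of freedom was 0.930 for fld libraries 1 and 3, 1.02 for fld 1 and 2 and 1.01 for ld 2 and 3. It was 0.596 for Col0 libraries 1 and 2 of set 3. None of these pairs differed beyond the full sampling noise of independent reads. A value as low as 0.596 lies under the noise of independent reads. In sets 1 and 2 the deposited values lacked 1 direction of variation within groups: the deviations of well-read genes had an SD of 0.000273 and 0.000286 along it, against 0.0321 and 0.0265 along the next, and in set 3 0.0127 against 0.0342. The lowest in apices was 0.0397. Raw counts divided by 1 factor per library would keep sampling noise along every direction. The counts of sets 1 and 2 had therefore also been changed gene by gene. How this was done is not given in the sources used here. Without this direction, the share of sampling noise left in the pairs named above was 0.528, 0.711, 0.618 and 0.131, in that order. Their chi-square values lay above it, also for genes with 10 to 400 reads (0.627, 0.809, 0.730 and 0.286). Because this direction lies within genotypes and lowers differences between replicates, the 3 libraries of each group were kept as separate samples. A fit with the closest libraries averaged as 1 sample is among the alternatives. Standard errors and p-values in the seedling sets may be too small for this reason.

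The labels give the same replicate numbers to every group. Numbers were taken to pair libraries where the deviations of all 3 same-numbered pairs correlated by more than 0.1, which held for ld with Col0 (0.271, 0.603 and 0.619) and pol2a with Col0 (0.399, 0.511 and 0.275) in apices. The labels name no shared day or batch. In set 2 the missing direction lowers the correlations of same-numbered libraries, so this rule could not show pairing there. In simulated data with 200 changed genes among the 19056, 19418 and 20991 genes of the ld comparisons of seedling sets 1 to 3, 80.3%, 83.6% and 87.9% of the 1.5-fold changes were recovered, and 93.9%, 93.9% and 92.5% of the 2-fold changes. In apices (18588 genes) 18.2% of 1.5-fold, 56.7% of 2-fold and 93.9% of 4-fold changes were recovered. Between 9 and 15 unchanged genes were called. The simulated seedling spreads came from the recovered counts, which lacked a direction of variation, so seedling recovery may be too high. With a simulated 2-fold shift of all genes, the spike-in scale called 18878, 19063 and 20893 genes with the shift alone in sets 1 to 3. These are true rises on that scale. It recovered 50.75% of the 1.5-fold and of the 2-fold changes. Genes lowered by these folds ended at or above Col0 after the shift, so they could not count as recovered. The median-of-ratios scale, which removes the shift, called 21, 9 and 18 genes with the shift alone. It recovered 85.1%, 76.1% and 86.6% of the 1.5-fold changes.

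Alternatives were pseudocounts of 0.5 and 5, no filter on low values, the median-of-ratios scale, the replicate number as a block, only the compared groups in the fit, each library left out in turn, DESeq2 1.42.0 (its Wald test, and its size factors in edgeR), an adjusted p threshold of 0.01 for overlaps, and other ways to sum the signal. Added after seeing the data were edgeR on the recovered reads, the missing direction as a covariate, averaging of the closest libraries, the slope of each apex library on gene length as a covariate, leaving out Col0 3 and ld 3 of the apex set together, and the block combined with only the compared groups. Testing the lists of ld and pol2a apices with the block, with only the compared groups and with both was also chosen then. edgeR on recovered reads called between 11624 and 19872 genes per seedling comparison, within 1.5 times of limma in each. No column was left without a sample (0). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.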

Results

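RNA was sequenced from 7-day-old Arabidopsis seedlings and from dissected shoot apices to ask whether LUMINIDEPENDENS (LD), a nuclear homeodomain protein of the autonomous flowering pathway, limits transcription broadly or at a few genes. Col0 is the wild type. The fld mutant lacks a histone demethylase-like partner of the same pathway. The pol2a mutant carries a mutation in the catalytic subunit of DNA polymerase epsilon. The seedling sets with a spike-in held Col0, fld and ld (set 1), Col0, ld, pol2a and ld pol2a (set 2), and Col0 and ld (set 3), with 3 libraries per group. The apex set held Col0, ld, pol2a and ld pol2a, also with 3 each and no spike-in. The design text calls the replicates biological, and no source used here says that they came from separate sowings. P-values measure only the spread between these libraries, which may be technical. In set 1, fld libraries 1 and 3 and ld libraries 2 and 3, and in set 3 Col0 libraries 1 and 2, differed by no more than the full sampling noise of independent reads. The values lacked a direction of variation within groups, and these pairs differed by more than the noise left without it. These libraries were therefore kept as separate samples. Counting them as 1 sample gave 18839 genes for fld and 18503 for ld in set 1 and 19628 in set 3, against 18891, 18604 and 19920.

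The targeted genes came first. Exon numbers count distinct annotated intervals over all transcripts of a gene, so they can exceed the exons of 1 transcript. FLD (AT3G10390, chromosome 3, 3229060 to 3232531, 9 exons, TAIR10.1) was at a signal of 64.5 ± 7.85 (SD, n = 3) in Col0 and 10.5 ± 5.40 in fld. It fell by 2.60 on the log2 scale (limma, adjusted p = 1.24e-12). LD (AT4G02560, chromosome 4, 1123475 to 1128490, 16 exons) was not lower in seedling libraries labelled ld on the spike-in scale. It was 64.6 ± 0.993 in Col0 and 367 ± 15.4 in ld in set 1. It was 182 ± 14.8 and 316 ± 14.8 in set 2, and 500.3 ± 29.3 and 674 ± 44.5 in set 3. Relative to the shift of all genes described next, the log2 change of LD in ld was 1.26 (limma, adjusted p = 3.1e-12), 0.23 (0.0584) and -0.26 (0.00256) in sets 1, 2 and 3. LD was also higher in fld of set 1 (358 ± 12.2, 0.80 above the shift, limma, adjusted p = 2.35e-09). In apices LD was 17.9 ± 3.35 CPM (counts per 1e6 reads) in Col0, 8.33 ± 3.64 in ld (edgeR, adjusted p = 0.0912) and 4.11 ± 0.716 in ld pol2a, where it fell by 2.11 (adjusted p = 0.000718). POL2A (AT1G08260, chromosome 1, 2588854 to 2606892, 50 exons) was 184 ± 0.259 in set 2 Col0 and 304 ± 14.9 in pol2a. This was a relative rise of 0.67 (limma, adjusted p = 1.29e-08). It was 19.1 ± 5.09 and 26.6 ± 5.16 CPM in apices (edgeR, adjusted p = 0.411). The alleles are not given in the sources used here, so the levels of LD and POL2A check no label. Here ld and pol2a stand throughout for the libraries so labelled.

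Summed over all genes, transcript signal was higher in fld, ld and ld pol2a than in Col0. The unit of the totals is 1e6. In set 1 the total was 6.13 ± 0.0635 in Col0, 17.8 ± 0.403 in fld (2.90-fold) and 13.3 ± 0.482 in ld (2.17-fold; mean ± SD, n = 3). In set 2 it was 12.1 ± 0.140 in Col0, 19.3 ± 0.172 in ld (1.60-fold), 13.3 ± 0.202 in pol2a (1.102-fold), and 35.7 ± 0.735 in ld pol2a (2.96-fold). In set 3 it was 26.1 ± 0.181 in Col0 and 42.2 ± 0.337 in ld (1.62-fold). The log2 differences were 1.53 ± 0.02 (SE) for fld, 1.12 ± 0.03, 0.68 ± 0.01 and 0.69 ± 0.01 for ld in sets 1, 2 and 3. They were 0.14 ± 0.02 for pol2a and 1.56 ± 0.02 for ld pol2a. No library of these groups overlapped with Col0. Each exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 allows. Over the 3 sets, ld was higher by a mean of 0.83 ± 0.14 (1.78-fold), with an exact two-sided permutation p of 0.00025 within sets (n = 9 per group), the smallest such permutations can give. Each library has 1 scale factor, so these differences rest on the factors, which were not analysed here. In sets 1 and 2 they may also rest on the unexplained change of the counts gene by gene.

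**Figure D1:**
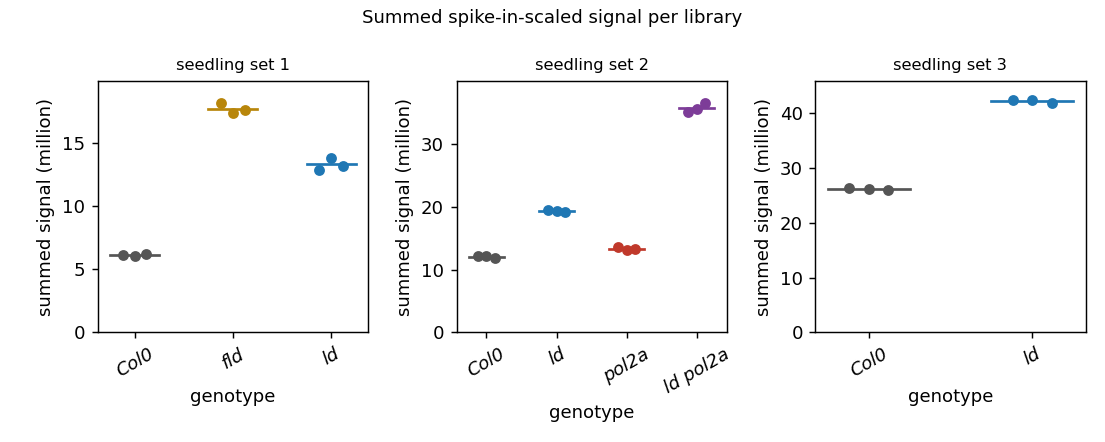
Summed signal (y axis, in 1e6, on the spike-in scale) of each library (points) by genotype (x axis) in the 3 seedling sets, with lines at the mean of 3 libraries. Means in set 1 were 6.13 in Col0, 17.8 in fld and 13.3 in ld; in set 2 pol2a lay at 13.3, near Col0 at 12.1, and ld pol2a at 35.7. The axes of the sets differ, and sets were scaled separately.

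In fld seedlings of set 1, nearly every gene was higher on the spike-in scale, and the flowering repressor FLC was among the genes with the highest fold. FLC (AT5G10140, chromosome 5, 3173382 to 3179448, 10 distinct annotated exon intervals) was 85.4 ± 8.13 in Col0 and 2795 ± 58.0 in fld (n = 3). This was 32.7-fold higher and 3.37 log2 units above the shift of all genes (limma, adjusted p = 7.37e-22). Other genes rose far above the shift: ICL, isocitrate lyase of the glyoxylate cycle (16.8 ± 4.07 to 546 ± 19.1), BCAT-2, a branched-chain amino acid aminotransferase (82.2 ± 12.4 to 2571 ± 32.7), and THA1, threonine aldolase (42.0 ± 7.33 to 1184 ± 70.2). So did the iron-deficiency regulators bHLH38 (18.4 ± 4.33 to 569.7 ± 53.3) and BHLH100 (24.3 ± 0.932 to 691 ± 66.2). QQS, an orphan gene of carbon and nitrogen partitioning, fell from 137 ± 20.3 to 18.6 ± 0.438. SOC1, a flowering promoter repressed by FLC, fell from 153 ± 4.18 to 85.1 ± 12.5. UAP56b (470.0 ± 26.9 to 156 ± 9.07), the stress gene RD29A (1700.3 ± 71.4 to 951 ± 57.8) and FAMT (67.3 ± 10.7 to 38.5 ± 4.12) also fell. UAP56b has a near-identical neighbouring copy, so its reads are uncertain.

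Of 19069 genes tested in fld against Col0 of set 1, limma called 18849 higher and 42 lower on the spike-in scale, with a median log2 change of 1.66. Relative to that shift it called 5599 higher and 5609 lower. Against the shift, 18 of 21 DNA replication and S phase genes rose and 1 fell (18 and 1 adjusted over the list alone; camera adjusted p = 5.24e-05, and adjusted p = 0.0456 with an estimated correlation). Examples were the histone genes HTR2 (284 ± 4.96 to 1623 ± 23.8, relative change 0.85) and HTR1 (398 ± 7.53 to 1896 ± 57.2, 0.59) and the ribonucleotide reductase gene RNR1 (269 ± 6.73 to 1005 ± 24.1, 0.24), each past limma's threshold. Photosynthesis genes lay below the shift. All 19 were called higher on the spike-in scale. Relative to the shift 16 fell and 2 rose (16 and 2 adjusted over the list alone; camera adjusted p = 2.97e-05). That call was lost with an estimated correlation (adjusted p = 0.418). RCA, Rubisco activase, shows the flip: its log2 change was 1.49 on the spike-in scale and -0.17 relative to the shift (limma, adjusted p = 2.2e-06). Of 12 abscisic acid and water stress genes, 7 fell and 2 rose relative to the shift (8 and 2 adjusted over the list alone; camera adjusted p = 0.00382, adjusted p = 0.316 with an estimated correlation). The cold-regulated dehydrin gene COR47 rose from 9543 ± 82.7 to 16503 ± 140 on the spike-in scale and lay 0.87 log2 units under the shift (-0.87). The 3 measured silenced loci fell relative to it (camera adjusted p = 0.0162, adjusted p = 0.233 with an estimated correlation). Relative to the shift 7 of 13 floral repressors rose and 4 fell (camera adjusted p = 0.184).

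**Figure D2:**
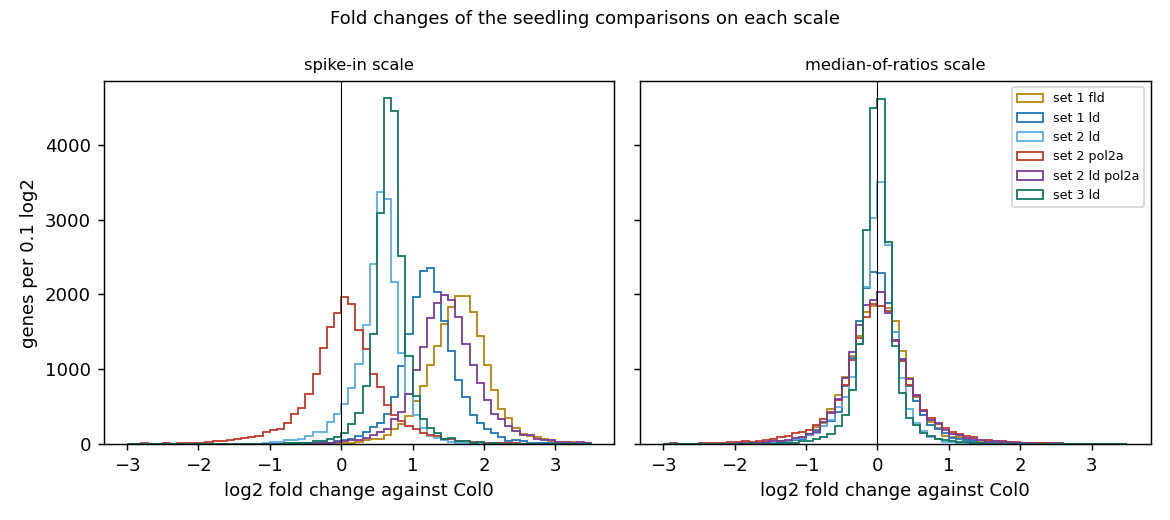
Numbers of genes (y axis, genes per 0.1 log2) by fitted log2 fold change against Col0 (x axis) in the 6 seedling comparisons (outlines), on the spike-in scale (left) and the median-of-ratios scale (right). On the left the medians lie at 1.66 for fld, 1.23, 0.56 and 0.69 for ld in sets 1, 2 and 3, 0.06 for pol2a and 1.48 for ld pol2a; on the right, where that shift is removed, each distribution centres near 0.

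In ld seedlings of set 1, FLC rose from 85.4 ± 8.13 to 1784 ± 42.6 (n = 3), 20.9-fold, or 3.14 log2 units above the shift (limma, adjusted p = 4.64e-21). MRD1, a short gene that overlaps HEI10 on the opposite strand, was at 0.757 ± 0.657 in Col0 and 467 ± 283 in ld, and HEI10, a meiotic crossover factor, at 8.01 ± 2.05 and 97.2 ± 19.99. Reads of the pair cannot be assigned with certainty. MRD1 lies at 19963047 to 19964712 and HEI10 at 19963267 to 19966952 on chromosome 1 (TAIR10.1), with 89.8% and 41.3% of their exon length shared. NAP5, an ABC transporter gene (5.94 ± 0.641 to 78.9 ± 7.77), HSD3, a hydroxysteroid dehydrogenase (26.6 ± 7.26 to 291 ± 21.2), and BCAT-2 (82.2 ± 12.4 to 919.9 ± 9.85) rose. QQS fell from 137 ± 20.3 to 16.3 ± 0.466, SOC1 from 153 ± 4.18 to 72.0 ± 2.59, and the cytochrome P450 gene CYP71A16 from 76.4 ± 7.46 to 35.5 ± 10.8. The low-sulphur genes ATSDI1 (58.7 ± 3.29 to 15.9 ± 2.19), LSU1 (58.5 ± 4.63 to 22.0 ± 4.88) and LSU3 (47.4 ± 3.64 to 15.9 ± 2.69) also fell. EMB975 rose from 48.5 ± 0.628 to 356 ± 24.4.

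For ld in set 1, limma called 18525 of 19069 genes higher and 79 lower on the spike-in scale (median log2 change 1.23). It called 4846 higher and 5263 lower relative to the shift. All 19 photosynthesis genes were higher on the spike-in scale. Relative to the shift 17 fell and 1 rose (17 and 1 adjusted over the list alone; camera adjusted p = 5.29e-05, adjusted p = 0.406 with an estimated correlation). PSBO1, of the oxygen-evolving complex, went from 26355 ± 172 to 58026 ± 1984, with a relative change of -0.10. Of 10 housekeeping genes 7 fell relative to the shift and none (0) rose (camera adjusted p = 0.00669), and of 12 abscisic acid genes 8 fell (0.00669), both at adjusted p = 0.406 with an estimated correlation. Of 12 mitosis genes, 6 rose (camera adjusted p = 0.0304, adjusted p = 0.406 with an estimated correlation). S phase genes did not stand apart (5 up and 2 down of 21, 4 and 2 adjusted over the list alone; camera adjusted p = 0.384). The genes encoded in the mitochondrion lay below the shift in this set, with medians of -1.24 in fld and -1.01 in ld. Their share of the signal was 1.93% to 1.99% in Col0, 0.741% to 0.788% in fld and 0.940% to 1.03% in ld.

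Between ld and fld, FLC was 1.57-fold higher in fld (2795 ± 58.0 against 1784 ± 42.6 in ld; log2 change of ld against fld -0.65, limma, adjusted p = 1.22e-10). FLD was 10.5 ± 5.40 in fld and 167 ± 4.81 in ld. limma called 485 genes higher and 13608 lower in ld (median -0.40), and 4281 higher and 4390 lower relative to that shift. Of 21 S phase genes, 16 were lower in ld relative to the shift and none (0) higher (17 adjusted over the list alone; camera adjusted p = 4.52e-06, adjusted p = 0.0237 with an estimated correlation). Across 19069 genes, which are not independent replicates, the log2 changes of ld and fld correlated with Pearson's r of 0.615 and Spearman's rho of 0.643. Both comparisons use the same 3 Col0 libraries, and unchanged groups simulated against such controls gave 0.501 and 0.460. The covariance was 0.131 against 0.00912 simulated. The 3 libraries cannot be split into 2 groups of 2, so part of the excess may come from the shared controls. Without a shared library, fld of set 1 correlated with ld of set 2 at r = 0.142 (rho = 0.0941) and with ld of set 3 at r = 0.223 (rho = 0.127). Between sets, ld of set 1 itself correlated with ld of sets 2 and 3 at r = 0.0476 and 0.175. The low values between sets therefore do not show that ld and fld share little.

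**Figure D3:**
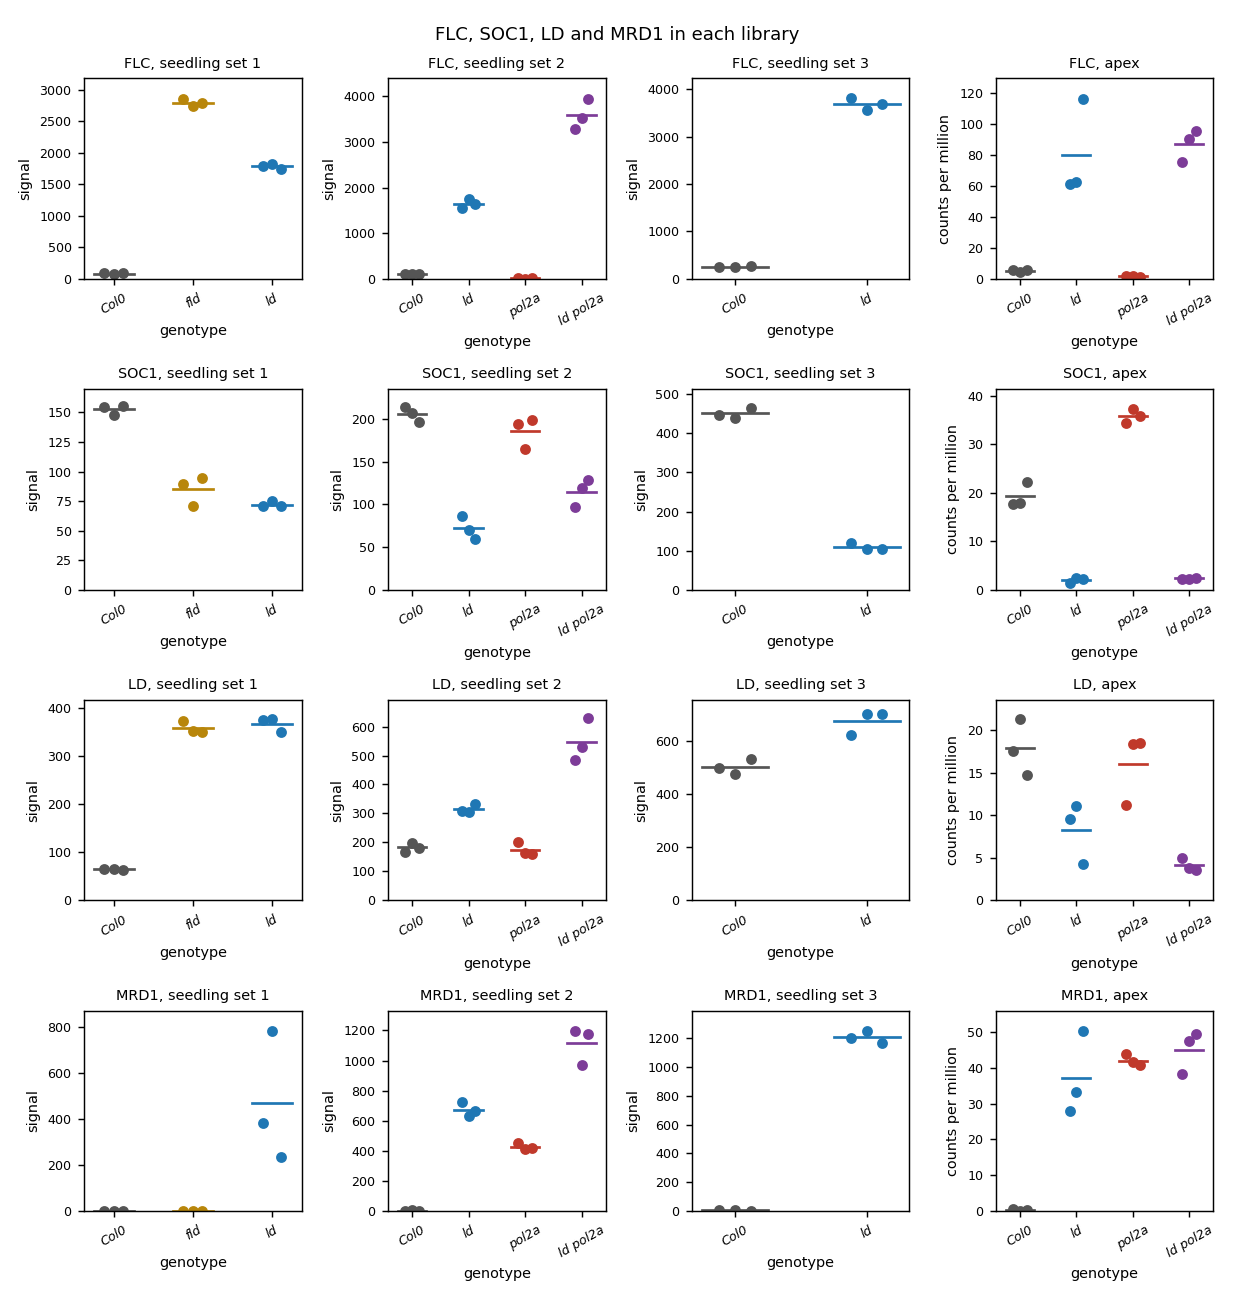
Levels of FLC, SOC1, LD and MRD1 (y axis, signal in seedlings, TMM-scaled CPM in apices) in each library (points) by genotype (x axis), with lines at the mean of 3. FLC is higher in ld and fld and lower in pol2a than in Col0 of the same set, SOC1 is lower in ld of all 4 sets (71.9 against 206 in set 2), and MRD1, near 0 in Col0 and in fld, is present in ld, pol2a and ld pol2a, with ld libraries of set 1 spread around 467.

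In ld seedlings of set 2, FLC rose from 104.2 ± 8.73 to 1649 ± 98.5 (n = 3), 15.8-fold and 3.41 log2 units above the shift (limma, adjusted p = 8.39e-13). MRD1 was 2.06 ± 1.64 in Col0 and 674 ± 49.5 in ld, and the overlapping HEI10 13.7 ± 3.61 and 80.9 ± 13.4. IPS1, a non-coding RNA induced by phosphate starvation, rose from 16.8 ± 1.38 to 284 ± 31.5. Rises were seen in the methyltransferase gene HOL2 from 142 ± 6.55 to 697 ± 23.3 and the methylesterase gene MES18 from 122 ± 3.39 to 576 ± 16.3. Among the largest falls were 3 genes known from iron deficiency: the iron transporter IRT1 from 188 ± 11.4 to 75.4 ± 5.58, BHLH100 from 9.14 ± 2.21 to 1.87 ± 1.39 and CYP82C4 from 17.3 ± 4.53 to 5.23 ± 3.38. QQS fell from 45.5 ± 9.03 to 8.99 ± 2.34, SOC1 from 206 ± 8.72 to 71.9 ± 13.5 and the splicing factor gene SR34b from 239 ± 18.5 to 96.6 ± 5.51. Of 19444 genes, limma called 15519 higher and 333 lower (median 0.56). It called 3537 higher and 3143 lower relative to the shift. Of 19 photosynthesis genes, 17 rose relative to the shift and 1 fell (17 and 1 adjusted over the list alone; camera adjusted p = 6.09e-12, adjusted p = 0.0213 with an estimated correlation). This was the opposite side of the shift from set 1. The antenna genes LHCB1.1 and LHCB2.1 went from 8086 ± 556 to 22568 ± 356 and from 3122 ± 112 to 8056 ± 84.5. Of 21 S phase genes, 15 rose and none (0) fell (17 adjusted over the list alone; camera adjusted p = 4.73e-07, adjusted p = 0.00606 with an estimated correlation). HTR1 rose from 791 ± 36.0 to 1599.9 ± 32.7. Polycomb components (2 up and 1 down of 8; camera adjusted p = 0.852) and the targets and autonomous pathway (4 up and 1 down of 12; 0.65) did not stand apart.

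In ld seedlings of set 3, FLC rose from 259 ± 6.37 to 3685 ± 128 (n = 3), 14.2-fold and 3.14 log2 units above the shift (limma, adjusted p = 1.37e-13). The FLC relative MAF5 rose from 31.9 ± 2.52 to 153 ± 9.49 and the MADS-box gene AGL67 from 21.8 ± 2.70 to 197 ± 21.4. So did the defensin gene PDF1.3 from 21.9 ± 5.77 to 118 ± 22.4 and SDC, an F-box gene silenced by DNA methylation, from 9.03 ± 0.975 to 55.5 ± 4.53. MRD1 was 4.50 ± 1.07 and 1207 ± 42.9, and HEI10 50.7 ± 2.50 and 1269 ± 30.3. SOC1 fell from 452 ± 13.2 to 109 ± 8.26, LBD26 from 113 ± 14.7 to 35.6 ± 1.26 and the cold-response regulator CBF2 from 118 ± 6.27 to 55.0 ± 2.65. MLO7 fell from 90.7 ± 4.08 to 44.2 ± 6.49, the potassium transporter HAK5 from 62.8 ± 4.75 to 38.3 ± 11.5 and the deadenylase gene CAF1a from 382 ± 16.3 to 241 ± 37.3. Of 20998 genes, limma called 19819 higher and 101 lower (median 0.69). It called 4022 higher and 4057 lower relative to the shift. Of 21 S phase genes, 13 rose relative to it and none (0) fell (13 adjusted over the list alone; camera adjusted p = 0.0022, adjusted p = 0.637 with an estimated correlation). HTR1 rose by 0.27 and RNR1 by 0.21. Both measured seed maturation genes rose (camera adjusted p = 0.221), and photosynthesis genes did not stand apart (4 up and 2 down of 19; camera adjusted p = 0.964). Chloroplast-encoded genes had a median of -0.55 relative to the shift, but their share of the signal did not part the groups (0.491% to 0.564% in Col0, and 0.398%, 0.286% and 0.557% in ld 1 to 3).

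Across the 3 seedling sets, which share no library, 14954 of 18832 genes were called in the same direction in ld. Of them 14949 were higher (14440 expected from independent lists) and 5 were lower (0.00429 expected). Relative to the shift the number was 836, with 407 higher (174 expected) and 429 lower (172 expected). The expected numbers take every gene as equally likely to be called. Genes read well in every set may be called more often, so the excess alone does not measure a shared response. Adding ld apices left 55 of 17584 genes, 54 higher (51.5 expected) and 1 lower, SOC1. With the seedling sets relative to the shift it was 31, with 18 higher (0.613 expected) and 13 lower (0.814 expected). On the spike-in scale, the 10 with the largest mean change were MRD1, FLC, AT5G14110, HEI10, AT4G15953, AT4G29990, AT4G00250, SOC1, AT1G72860 and EMB975. AT4G29990 was not among the 31 relative to the shift, and QQS (mean -2.295) took its place in the first 10. AT5G14110 went from 6.11 ± 1.27 to 87.0 ± 7.80 in set 1 and from 23.3 ± 3.06 to 236 ± 37.3 in set 2. It went from 32.3 ± 3.55 to 449 ± 30.4 in set 3 and from 0.493 ± 0.227 to 4.66 ± 3.28 CPM in apices. The apex call of AT5G14110 was lost without Col0 1 (edgeR, adjusted p = 0.191), Col0 2 (0.11) or ld 2 (0.0995). EMB975 was 3.54-fold higher in set 2 and 3.22-fold in set 3 and 2.03-fold in apices. The apex call of EMB975 was lost without Col0 1 (edgeR, adjusted p = 0.191), Col0 2 (0.115), ld 1 (0.0674) or ld 2 (0.0761). AT4G29990, a receptor-like kinase gene, was called in set 2 on the spike-in scale alone (19.7 ± 2.18 to 38.0 ± 5.61; relative change 0.37, limma, adjusted p = 0.107). Across genes, the log2 changes of ld correlated at r = 0.0476 between sets 1 and 2, 0.175 between sets 1 and 3, 0.366 between sets 2 and 3, and 0.455, 0.0097 and 0.140 between apices and sets 1, 2 and 3 (rho = -0.0221, 0.0382, 0.290, 0.402, -0.076 and -0.0397).

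In pol2a seedlings of set 2, genes of the DNA damage response rose and FLC fell. FLC was 104.2 ± 8.73 in Col0 and 12.6 ± 4.23 in pol2a (n = 3), a relative log2 change of -3.09 (limma, adjusted p = 3.07e-13). SMR7, a cyclin-dependent kinase inhibitor induced by DNA damage, rose from 5.56 ± 1.84 to 136 ± 5.90. TSO2, a ribonucleotide reductase subunit, rose from 416 ± 3.38 to 2890 ± 53.8, and the repair genes PARP2 and BRCA1 from 53.0 ± 0.953 to 339 ± 42.8 and from 56.3 ± 3.92 to 256 ± 18.9. PCC1 (105.3 ± 5.01 to 1924 ± 115) and LURP1 (29.9 ± 3.73 to 435 ± 15.5), known from pathogen responses, rose. So did the low-sulphur gene ATSDI1 (11.7 ± 2.53 to 189 ± 24.7) and the Nudix hydrolase gene NUDT24 (3.34 ± 1.55 to 62.2 ± 11.7). MRD1 was 2.06 ± 1.64 and 429 ± 22.0. The dark-inducible genes DIN11 (552 ± 21.5 to 18.6 ± 4.34) and ASN1, asparagine synthetase (4286 ± 130 to 201 ± 25.8) fell, as did BCAT-2 (744 ± 23.8 to 31.8 ± 5.74) and CYP71B22 (75.2 ± 10.5 to 2.51 ± 0.912). The defensin gene PDF1.2c was 104.8 ± 19.8 in Col0 and 0.328 ± 0.568 in pol2a. GLC was 37.2 ± 3.58 in Col0 and listed at 0 in the 3 pol2a libraries.

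Of 19444 genes in pol2a of set 2, limma called 6620 higher and 4896 lower, with a median log2 change of 0.06. It called 5841 higher and 5806 lower relative to it. Relative to that small shift, 19 of 23 DNA damage genes rose and none (0) fell (19 adjusted over the list alone; camera adjusted p = 5.23e-08, adjusted p = 0.00318 with an estimated correlation). Likewise 14 of 21 S phase genes rose and none (0) fell (16 adjusted over the list alone; 7.31e-05 and adjusted p = 0.0109 with an estimated correlation). All 6 heat shock genes rose (camera adjusted p = 0.00229, adjusted p = 0.0442 with an estimated correlation). Among them were HSP90.1 (985 ± 120 to 2813 ± 67.8), HSP101 (265 ± 17.5 to 752 ± 23.6) and their regulator HSFA2 (47.7 ± 4.05 to 222 ± 19.3). Floral organ identity genes, which Polycomb keeps silent in leaves, rose in 6 of 7 cases (camera adjusted p = 0.00814, adjusted p = 0.0806 with an estimated correlation). SEP3 went from 55.5 ± 8.82 to 535 ± 35.8 and SEP1 from 2.09 ± 1.40 to 32.5 ± 8.95. Immunity genes (8 up and 1 down of 13; camera adjusted p = 0.01) included SARD1 (12.01 ± 2.04 to 99.0 ± 7.60) and WRKY70 (116 ± 5.26 to 304 ± 13.1). The call was lost with an estimated correlation (adjusted p = 0.0806). Photosynthesis genes (16 up and 3 down of 19; camera adjusted p = 0.000215) and abscisic acid genes (7 up and 1 down of 12; 0.0167) lost theirs too (adjusted p = 0.114 and adjusted p = 0.222 with an estimated correlation). Circadian clock genes (2 up and 6 down of 11; camera adjusted p = 0.0626), root markers (2 up and 4 down of 9; 0.288), shoot meristem genes (3 up and 1 down of 7; 0.163) and floral promoters (2 up and 4 down of 8; 0.513) were not called.

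In ld pol2a seedlings, FLC was 3586 ± 333 against 104.2 ± 8.73 in Col0 (n = 3), 34.4-fold, a relative rise of 3.61 (limma, adjusted p = 5.56e-14). It lay with ld and not with pol2a. Relative to the shift it did not differ from ld (0.20, adjusted p = 0.263), while on the spike-in scale it was 2.17-fold higher than in ld (adjusted p = 4.88e-07). SMR7 was 5.56 ± 1.84 in Col0 and 668 ± 35.8 in ld pol2a, and TSO2 416 ± 3.38 and 12327 ± 209, each a rise. PARP2 rose from 53.0 ± 0.953 to 1107 ± 109, and BRCA1 rose from 56.3 ± 3.92 to 823 ± 47.1. NUDT24 (3.34 ± 1.55 to 249 ± 17.04), ATSDI1 (11.7 ± 2.53 to 559 ± 53.7), LSU3 (9.84 ± 2.19 to 405 ± 31.8) and the glucosidase gene BGLU28 (2.96 ± 0.664 to 164 ± 11.6) rose. MRD1 was 2.06 ± 1.64 and 1114 ± 127. THA1 fell from 536 ± 12.6 to 75.6 ± 25.1, the glyoxalase gene GLYI7 from 86.6 ± 4.71 to 30.0 ± 5.08, and DIN11 from 552 ± 21.5 to 221 ± 48.0. Falls were also seen in the myrosinase gene TGG2 from 3683 ± 115 to 1617 ± 30.8, the peroxiredoxin gene TPX2 from 728 ± 52.7 to 321 ± 9.95 and BCAT-2 from 744 ± 23.8 to 331 ± 35.9. limma called 19041 of 19444 genes higher and 68 lower (median 1.48). It called 5681 higher and 5507 lower relative to the shift. Relative to it, 19 of 23 DNA damage genes rose and none (0) fell (19 adjusted over the list alone; camera adjusted p = 8.02e-10, adjusted p = 0.00154 with an estimated correlation). So did 17 of 21 S phase genes (camera adjusted p = 4.45e-06, adjusted p = 0.00565 with an estimated correlation). So did 11 of 12 mitosis genes (camera adjusted p = 0.000401, adjusted p = 0.0198 with an estimated correlation), among them CDC20.1 (165 ± 10.1 to 847 ± 45.5). Of 19 photosynthesis genes 16 rose (camera adjusted p = 2.77e-08, adjusted p = 0.0332 with an estimated correlation). Floral organ identity genes (5 up of 7; camera adjusted p = 0.0206) and abscisic acid genes (1 up and 7 down of 12; 0.0246) lost their calls with an estimated correlation (adjusted p = 0.108 and adjusted p = 0.27). RNA polymerase II and elongation genes (3 up and 10 down of 16) were not called as a list (camera adjusted p = 0.0603).

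Set against the single mutants, ld pol2a had higher QQS and BHLH100. QQS was 8.99 ± 2.34 in ld, 16.0 ± 2.80 in pol2a and 1183 ± 96.5 in ld pol2a. BHLH100 was 1.87 ± 1.39, 3.18 ± 0.340 and 314 ± 19.6 (n = 3 each). CYP82C4 rose from 5.23 ± 3.38 in ld to 451 ± 27.5. In contrast MIOX4 (1141 ± 198 to 197 ± 17.05), GAT1_2.1 (1691 ± 86.7 to 332 ± 42.5) and IPS1 (284 ± 31.5 to 61.0 ± 2.65) fell. Against pol2a, COR15A (3139 ± 110 to 1359 ± 95.9), HSFA2 (222 ± 19.3 to 97.0 ± 13.9), the lipase gene TLL1 (8406 ± 49.0 to 4879 ± 136) and the chaperone gene ATERDJ3A (157 ± 6.31 to 94.5 ± 4.78) fell. limma called 18272 genes higher and 226 lower against ld (median 0.93; 5946 and 5755 relative to it). It called 19077 higher and 34 lower against pol2a (median 1.42; 5245 and 5307). All 12 mitosis genes rose relative to the shift against ld (camera adjusted p = 0.000148, adjusted p = 0.0171 with an estimated correlation). Against pol2a, 11 of 12 abscisic acid genes fell relative to the shift (camera adjusted p = 3.42e-05, adjusted p = 0.125 with an estimated correlation). The interaction, which asks whether the effect of ld differs with pol2a, was called for 16824 genes upwards and 306 downwards (median 0.86; 4965 and 5044 relative to it). It was 3.29 for FLC relative to the shift (limma, adjusted p = 1.04e-10). It was 7.51 for QQS, 7.32 for BHLH100, 5.53 for the iron transporter IRT1, and 5.32 for the ferric reductase FRO2. It was -5.05 for IPS1, -2.68 for ATERDJ3A and -2.64 for the endoplasmic reticulum chaperone BIP3, all past limma's threshold. LD, FLD and POL2A had positive interactions on the spike-in scale (0.85, 0.60 and 0.51) and negative values relative to the shift (-0.02, -0.26 and -0.36).

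In ld apices, FLC rose from 5.39 ± 0.677 to 80.0 ± 31.4 CPM (n = 3; log2 change 3.89 ± 0.28 SE, edgeR, adjusted p = 2.56e-05). SOC1 fell from 19.3 ± 2.48 to 1.92 ± 0.567 (-3.33 ± 0.18, 2.33e-06). MAF5 rose from 1.94 ± 0.684 to 6.09 ± 1.39 and ML3, a MEI2-like gene, from 4.46 ± 0.326 to 15.0 ± 8.64. HSD3 rose from 2.54 ± 0.0433 to 5.57 ± 0.425 and the glucosinolate gene CYP79F2 from 4.38 ± 0.209 to 9.51 ± 2.76. MRD1 was 0.273 ± 0.163 and 37.1 ± 11.7, and HEI10 1.88 ± 0.691 and 5.48 ± 0.457. TLL1 (80.6 ± 34.2 to 21.8 ± 6.86), the glucosinolate-breakdown gene ESP (30.0 ± 8.95 to 12.4 ± 1.71), and FDM2, of RNA-directed DNA methylation (12.1 ± 0.816 to 5.03 ± 0.791), fell. So did the histone deacetylase gene HDA18 (2.25 ± 0.571 to 1.00 ± 0.192) and the protease gene CP1 (2.32 ± 0.171 to 1.061 ± 0.238). Floral repressors rose as a list (2 up of 13, FLC and MAF5, 4 up and 1 down adjusted over the list alone; camera adjusted p = 6.67e-05, adjusted p = 0.0131 with an estimated correlation). Floral promoters fell (1 down of 9, SOC1, 2 adjusted over the list alone; camera adjusted p = 4.36e-06, adjusted p = 0.0131 with an estimated correlation). AGL24 was 6.14 ± 0.299 and 3.804 ± 0.436 (edgeR, adjusted p = 0.0525). AGL24 passed with the replicate number as a block (-0.69, adjusted p = 0.0464), with the DESeq2 Wald test (adjusted p = 0.0245), without ld 3 (edgeR, adjusted p = 0.0141) and with the length slope as a covariate (edgeR, adjusted p = 0.00392). With only the compared groups in the fit, SOC1 was the 1 promoter of 7 called lower, so AGL24 did not pass. With the block as well, 1 of 7 promoters was called lower. fry's adjusted p for both lists was 0.000101. For repressors and promoters it was 0.00101 and 0.00048 with the replicate number as a block, 0.00237 and 0.0157 with only the compared groups in the fit, and 0.0553 for each with both changes. Camera with an estimated correlation gave adjusted p = 0.0264 for both lists with the block, 0.162 and 0.204 with only the compared groups, and 0.392 for both with both changes. fry's adjusted p for S phase genes, downwards, was 0.323, and 0.201 with the block, 0.551 with only the compared groups and 0.0315 with both. Of the named genes, edgeR's call was lost by 17 without Col0 1 (adjusted p 0.0681 to 0.239), 16 without Col0 2 (0.0582 to 0.147) and 4 without Col0 3 (0.0541 to 0.0619). It was lost by 14 without ld 1 (0.0546 to 0.139) and 16 without ld 2 (0.0512 to 0.181), while FLC, SOC1 and MRD1 passed each time. With no filter on low counts ML3, TLL1, CP1 and QQS lost it (adjusted p 0.0528 to 0.0988 in edgeR). S phase (0.00463), photosynthesis (0.00237) and abscisic acid genes (0.0033), with no member called (0) and lower medians (-0.24, -0.20 and -0.77), lost camera's call with an estimated correlation (adjusted p = 0.774, adjusted p = 0.774 and adjusted p = 0.656).

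Of 18705 genes in ld apices, edgeR called 71 higher and 110 lower (3577 at an unadjusted p under 0.05). The number rested on single libraries and on the fit. It was 10 without Col0 1, 18 without Col0 2, 324 without Col0 3, 19 without ld 1, 18 without ld 2 and 2525 without ld 3. It was 524 with the replicate number as a block, 5 with only the compared groups in the fit, 809 with DESeq2, and 2811 with the slope on gene length as a covariate, chosen after seeing the data. With only the compared groups, 17 of the named genes lost their calls (adjusted p 0.159 to 0.268 in edgeR) and FLC, SOC1 and MRD1 did not. With the block as well, 4 of the named genes lost theirs (edgeR, adjusted p 0.0507 to 0.0806). The apex libraries differed in how counts depended on gene length, from -0.261 log2 per doubling of length in ld 3, -0.137 in pol2a 1 and -0.0896 in Col0 3 to 0.156 in ld 1.

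**Figure D4:**
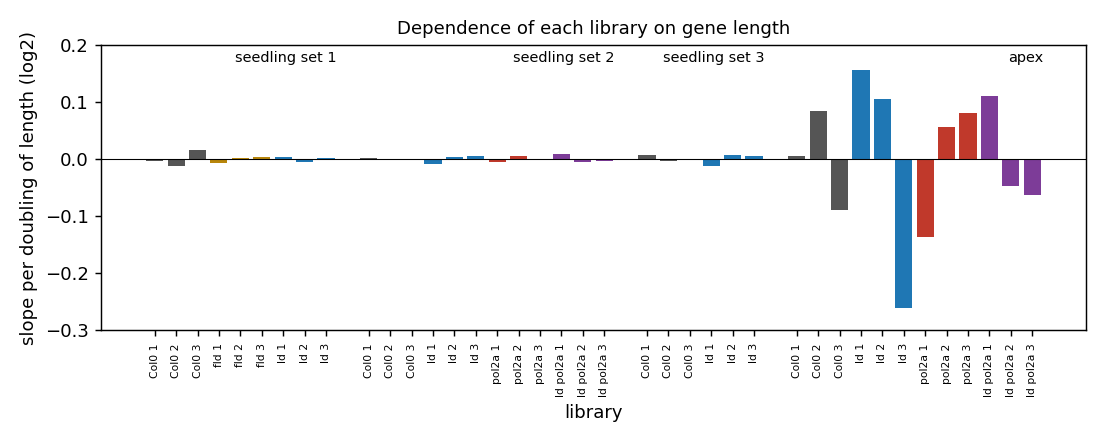
Slope of each library's deviation from its group mean on gene length (y axis, log2 per doubling of length) for the 39 libraries (bars, in groups by set and genotype along the x axis). Seedling libraries lie near 0, and apex libraries range from -0.261 (ld 3) to 0.156 (ld 1).

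In pol2a apices, DNA damage genes rose, and the wax gene CER1 and the cutin gene CYP86A4 were among the largest falls. SMR7 rose from 0.339 ± 0.0644 to 18.3 ± 2.46 CPM (n = 3; log2 change 5.71 ± 0.23 SE, edgeR, adjusted p = 1.75e-08). TSO2 rose from 79.9 ± 7.37 to 794 ± 19.5 and the DNA damage regulator ANAC044 from 1.69 ± 0.435 to 16.2 ± 1.81. Rises were also seen in the thymidine kinase gene TK1a from 20.7 ± 4.82 to 167 ± 18.8 and HDA18 from 2.25 ± 0.571 to 31.1 ± 0.982. CER1, of wax alkane synthesis, fell from 67.9 ± 11.3 to 3.38 ± 1.65, the cutin hydroxylase gene CYP86A4 from 26.7 ± 5.83 to 1.19 ± 0.131. ESM1, a modifier of glucosinolate breakdown, fell from 296 ± 59.1 to 10.2 ± 3.82 and the pectin methylesterase gene PME61 from 12.5 ± 2.19 to 0.322 ± 0.239. GLC was 14.5 ± 3.68 in Col0 and 0.0480 ± 0.0416 in pol2a, and MYB23, a trichome regulator, 5.60 ± 0.445 and 0.0269 ± 0.0465. FLC fell from 5.39 ± 0.677 to 1.58 ± 0.566 (-1.77 ± 0.34, adjusted p = 0.0102). MAF5 fell from 1.94 ± 0.684 to 0.520 ± 0.0358 and MAF4 from 1.64 ± 0.426 to 0.595 ± 0.130. SOC1 rose from 19.3 ± 2.48 to 35.9 ± 1.44 and AGL24 from 6.14 ± 0.299 to 9.46 ± 0.903. AGL24 lost its call without Col0 1 (edgeR, adjusted p = 0.0727), Col0 2 (0.103), Col0 3 (0.0536), pol2a 1 (0.085) or pol2a 2 (0.0684), and MAF4 without Col0 3 (0.055) or pol2a 2 (0.073). With only the compared groups in the fit, 2 of the named genes lost edgeR's call (adjusted p 0.0504 to 0.061). Floral repressors then had 2 down of 13 and floral promoters 1 up of 8. MRD1 was 0.273 ± 0.163 and 42.0 ± 1.59.

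Among lists in pol2a apices, 20 of 24 DNA damage genes rose and none (0) fell (21 adjusted over the list alone; camera adjusted p = 4.54e-80, adjusted p = 4.23e-05 with an estimated correlation). They included the repair genes RPA1E (3.82 ± 0.366 to 18.24 ± 1.24) and XRI1 (9.52 ± 0.810 to 45.8 ± 4.72). Of 6 floral organ identity genes, 4 rose (5 adjusted over the list alone; camera adjusted p = 8.3e-08, adjusted p = 0.0033 with an estimated correlation). With an estimated correlation, the block and only the compared groups, camera's adjusted p was 0.0483 for DNA damage and 0.311 for organ identity genes, the latter no longer called. SEP3 went from 3.77 ± 1.04 to 8.07 ± 1.60, and SEP1 and AG, near 0 in Col0, were at 1.38 ± 0.346 and 1.26 ± 0.222. SEP3 lost its call without Col0 1 (edgeR, adjusted p = 0.0616), pol2a 2 (0.0513) or pol2a 3 (0.0578). Floral promoters (2 up of 9; camera adjusted p = 0.0292), S phase genes (4 up of 21; 6.77e-07) and mitosis genes (4 up of 12; 0.00117) lost their calls (adjusted p = 0.146, 0.256 and 0.227 with an estimated correlation). RNA polymerase II genes (4 down of 16; camera adjusted p = 0.0267) and shoot meristem genes (2 up of 8; 0.02) lost theirs at adjusted p = 0.104 with an estimated correlation. Floral repressors (3 down of 13) had camera adjusted p = 0.0731. Of 12 trichome genes, a list written after these values were seen, 6 fell and none (0) rose in edgeR. GL2 was at 21.8 ± 6.43 in Col0 and 2.24 ± 0.926 in pol2a and GL1 at 2.81 ± 0.199 and 0.722 ± 0.239. In pol2a seedlings of set 2, 6 of 8 fell and 1 rose relative to the shift. GL2 fell from 164 ± 5.53 to 32.8 ± 2.62. edgeR called 693 of 18705 genes higher and 436 lower in pol2a apices. The total of 1129 was 538 without Col0 1, 515 without Col0 2, 640 without pol2a 1, 528 without pol2a 2, 693 with only the compared groups in the fit and 3187 with the length slope as a covariate.

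In ld pol2a apices, DNA damage genes and FLC rose, and no trichome gene was called against Col0 (0 by edgeR). FLC rose from 5.39 ± 0.677 to 87.0 ± 10.4 CPM (n = 3; 4.01 ± 0.28 SE, edgeR, adjusted p = 3.89e-06). SMR7 rose from 0.339 ± 0.0644 to 15.4 ± 1.91 and ANAC044 from 1.69 ± 0.435 to 23.3 ± 4.28. HDA18 rose from 2.25 ± 0.571 to 26.0 ± 1.01 and FTM1 from 1.52 ± 1.33 to 23.5 ± 8.25. MRD1 was 45.1 ± 6.07. SOC1 fell from 19.3 ± 2.48 to 2.30 ± 0.133, ESM1 from 296 ± 59.1 to 24.1 ± 2.19 and the repair endonuclease gene UVH3 from 7.42 ± 1.01 to 0.712 ± 0.238. Falls were also seen in the ferric reductase gene FRO6, from 29.9 ± 4.71 to 3.02 ± 1.18, the proline synthesis gene P5CS1, from 137 ± 81.1 to 17.2 ± 8.24, and TGG2, from 545 ± 53.4 to 73.4 ± 35.8. Of 24 DNA damage genes, 20 rose and none (0) fell (21 adjusted over the list alone; camera adjusted p = 2.22e-40, adjusted p = 0.000591 with an estimated correlation). TSO2 rose from 79.9 ± 7.37 to 849.6 ± 76.1. Camera's calls for photosynthesis (10 down of 19; adjusted p = 2.84e-08), abscisic acid (6 down of 11; 0.00281) and S phase (8 up of 21; 1.33e-06) were lost, each at adjusted p = 0.34 with an estimated correlation. Floral promoters (2 down of 9; camera adjusted p = 0.00281) and mitosis genes (4 up of 12; 0.0311) lost theirs (adjusted p = 0.11 and adjusted p = 0.385 with an estimated correlation). So did root markers (2 up of 6; camera adjusted p = 0.0311) and floral organ identity genes (3 up of 6; 0.0478; adjusted p = 0.198 and adjusted p = 0.207 with an estimated correlation). The floral repressors went both ways, with 2 up and 2 down of 13, a lower median (-0.09), a higher mean (0.16) and camera adjusted p = 0.789. MAF5 rose from 1.94 ± 0.684 to 3.67 ± 0.459. SVP (62.9 ± 11.1 to 31.2 ± 0.943) and SNZ (12.4 ± 2.32 to 5.03 ± 0.287) fell. MAF5 lost its call without Col0 1 (edgeR, adjusted p = 0.0919), Col0 2 (0.0914), ld pol2a 2 (0.0841) or ld pol2a 3 (0.0781). edgeR called 2774 genes higher and 2033 lower. The total of 4807 was 2816 without ld pol2a 2, 2727 without ld pol2a 3 and 7832 with the length slope as a covariate.

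**Figure D5:**
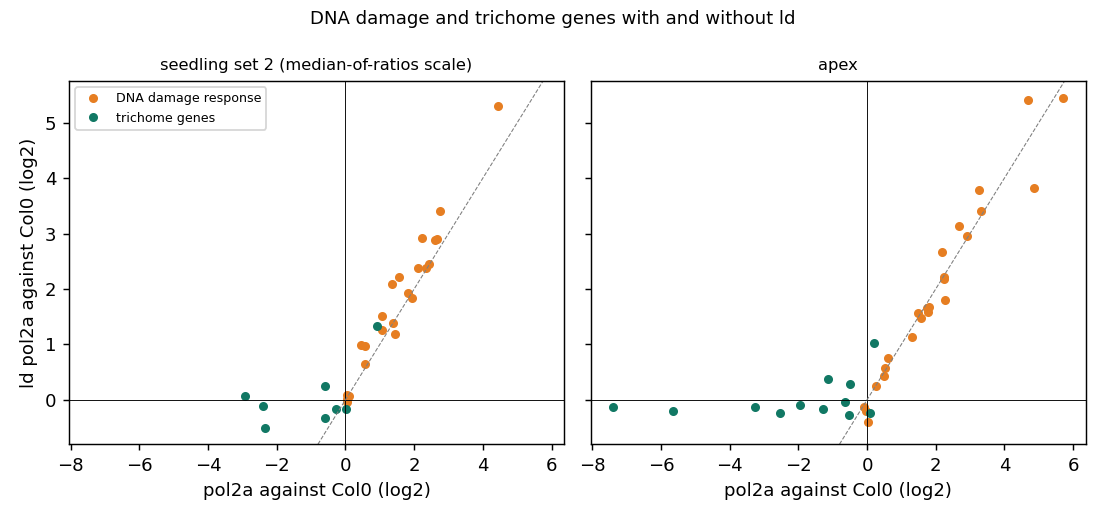
Log2 change against Col0 in pol2a (x axis) and in ld pol2a (y axis) of each measured DNA damage gene and trichome gene (points), in seedling set 2 relative to the median shift (left) and in apices (right); the dashed line marks equal change. DNA damage genes called higher number 19 of 23 (left) and 20 of 24 (right) in pol2a and as many in ld pol2a. On the left their medians are 1.45 in pol2a and 1.83 in ld pol2a, and 9 of 23 were called higher in ld pol2a than in pol2a. Trichome genes called lower number 6 of 8 in pol2a and 3 of 8 in ld pol2a (left), and 6 of 12 and 0 of 12 (right). The trichome list was written after the values were seen.

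Against ld, ld pol2a apices had higher SMR7 (0.448 ± 0.115 to 15.4 ± 1.91), HDA18 (1.00 ± 0.192 to 26.0 ± 1.01), ANAC044 (1.08 ± 0.473 to 23.3 ± 4.28) and TSO2 (68.2 ± 6.18 to 849.6 ± 76.1). They had lower UVH3 (10.6 ± 4.23 to 0.712 ± 0.238), ESM1, TGG2 and FRO6. FLC did not differ (0.12 ± 0.23 SE, edgeR, adjusted p = 0.712). Against pol2a, FLC (1.58 ± 0.566 to 87.0 ± 10.4) and FTM1 (0.496 ± 0.301 to 23.5 ± 8.25) rose. SOC1 (35.9 ± 1.44 to 2.30 ± 0.133), UVH3 (6.23 ± 1.73 to 0.712 ± 0.238), FRO6 and CYP706A6 (12.8 ± 3.84 to 2.39 ± 0.706) fell. Against pol2a, 4 of 9 floral promoters fell (5 adjusted over the list alone; camera adjusted p = 7.55e-09, adjusted p = 0.00834 with an estimated correlation). GLC was 0.0480 ± 0.0416 in pol2a and 9.48 ± 1.27 in ld pol2a, MYB23 0.0269 ± 0.0465 and 5.16 ± 0.877. GL2 rose from 2.24 ± 0.926 to 20.03 ± 1.43. Of the 12 trichome genes, chosen after the values were seen, edgeR called 7 higher than in pol2a and none (0) apart from Col0. In ld pol2a of set 2, limma called 3 of 8 trichome genes lower and 1 higher than in Col0 relative to the shift. Against pol2a, 5 of 8 rose relative to the shift. GL2 rose from 32.8 ± 2.62 to 324 ± 30.96. edgeR called 3415 genes higher and 2948 lower against ld, and 1576 and 1102 against pol2a. The first total, 6363, was 4135 without ld 2, 3862 without ld pol2a 2 and 3955 without ld pol2a 3. The second, 2678, was 1225 without pol2a 2, 1117 without ld pol2a 2, 966 without ld pol2a 3 and 5474 with the length slope as a covariate.

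The effect of ld differed with pol2a in apices for FLC (interaction 1.89 ± 0.41 SE, edgeR, adjusted p = 0.0189), GL2 (2.80 ± 0.37, 0.002), the proline-rich protein gene PRP2 (2.08 ± 0.24, 0.000869) and NAC13 (2.06 ± 0.26, 0.00173). It differed in the other direction for UVH3 (-3.58 ± 0.49, 0.00239), ORG1 (-3.47 ± 0.45, 0.00183), the superoxide dismutase gene CSD2 (-3.90 ± 0.88, 0.022) and the sucrose transporter SWEET12 (-2.48 ± 0.55, 0.0203). CSD2 lost its call with no filter on low counts (edgeR, adjusted p = 0.0576) and without Col0 1 (0.0668), ld 1 (0.0525), ld 2 (0.0544), pol2a 2 (0.0694), ld pol2a 2 (0.0658) or ld pol2a 3 (0.0692). FLC lost it without Col0 1 (0.0547), pol2a 3 (0.0591), ld pol2a 2 (0.0536) or ld pol2a 3 (0.0568). SWEET12 lost it without Col0 1 (0.0559), ld pol2a 2 (0.0522) or ld pol2a 3 (0.0663). LD (-0.85 ± 0.43, adjusted p = 0.247) did not pass. edgeR called 959 interactions upwards and 451 downwards among 18705 genes. The total of 1410 was 535 without Col0 1, 631 without Col0 2, 887 without ld 1, 630 without ld 2, and 3619 without ld 3. It was 528 without pol2a 2, 754 without pol2a 3, 494 without ld pol2a 2, 505 without ld pol2a 3 and 4507 with the length slope as a covariate. Across 17926 genes, the changes in seedlings of set 2 and in apices correlated at r = 0.286 for pol2a (rho = 0.162), 0.372 for ld pol2a (rho = 0.347) and -0.0439 for the interaction (rho = -0.0539); genes are not independent replicates.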

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

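The choice of these 3 results followed the values. In seedlings of set 2 the effect of ld with and without pol2a differed for 17130 genes by limma, and relative to the shift of all genes for 10009. The summed signal was 1.60-fold higher in ld than in Col0 and 2.96-fold higher in ld pol2a than in Col0, while pol2a lay at 1.102-fold. In apices, which have no spike-in, the effect of ld differed with pol2a for 1410 genes by edgeR.

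LD in ld against Col0 was higher in set 1 and lower in apices, in every sample, as reads per 1e6 reads: 27.6 ± 1.32 in ld and 10.5 ± 0.271 in Col0 of set 1, and 9.15 ± 4.73 and 17.57 ± 4.53 in apices (n = 3). The 2 log2 changes differed by 2.33 (not tested). By edgeR the fall of LD in ld apices was not called. The lowest apex library, ld 3 (4.23 CPM, against 9.61 and 11.2 in ld 1 and ld 2), also had the steepest slope on gene length (-0.261). Among seedlings, LD lay higher in ld in set 1 alone: the log2 ratio was 0.11 in set 2, with overlapping samples, and -0.26 in set 3, lower in every sample. In set 1 LD was also higher in fld than in Col0 (signal 358 ± 12.2 against 64.6 ± 0.993, n = 3; 0.80 above the shift, limma, adjusted p = 2.35e-09), so the rise there was not particular to ld. Tissue alone therefore does not account for it, and the cause is open.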

How the results depend on the processing

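Of the alternatives, the slope on gene length, the fit without both Col0 3 and ld 3, the block with only the compared groups, edgeR on recovered reads, the missing direction as a covariate and the averaging of the closest libraries were chosen after seeing the data. The values fall on 26 results and 297 values of named genes. For counts, levels and correlations 245 settings kept the result and 56 moved it. The bound of 1.5-fold applied to counts of genes alone. Summed signals and correlations were labelled as kept unless the sign changed or, for summed signals, the permutation call changed. With 3 against 3 libraries the smallest permutation p is 0.1, so that call could not change. Settings of summed signals and correlations therefore say little about how far these values moved. For named genes 4085 kept the call, 143 lost it, 23 gained it and 12 reversed the sign.

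On the median-of-ratios scale the counts were 11208 for fld and 10109 for ld in set 1, 8671 for ld against fld, 6680 for ld in set 2, 11188 for ld pol2a against Col0, 11701 against ld and 10552 against pol2a, 10009 for the interaction and 8079 for ld in set 3. The genes called in all 3 seedling sets were 836, and 31 with apices. Signs reversed for RCA (-0.168) and COR47 (-0.871) in fld, and PSBO1 (-0.105) in ld of set 1. They also reversed for FLD in ld pol2a against Col0 (-0.375), ld (-0.428) and pol2a (-0.205), LD against ld (-0.134), and POL2A against pol2a (-0.168). The interactions of LD (-0.016), FLD (-0.258) and POL2A (-0.356) in set 2 and LD in ld of set 3 (-0.26) reversed too. This follows from the shift of all genes.

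For ld apices, where edgeR called 181 genes, the count was 114 with no filter, 809 with the DESeq2 Wald test, 524 with the replicate block, 5 with only the compared groups, 2811 with the slope on gene length as a covariate, 1944 without both Col0 3 and ld 3, and 318 with block and compared groups. For pol2a apices (1129) it was 693 with only the compared groups, 3187 with the slope, 1991 without Col0 3 and ld 3, and 1715 with block and compared groups. The slope gave 7832 for ld pol2a against Col0, 5474 against pol2a and 4507 for the interaction, and leaving out Col0 3 and ld 3 gave 4367 against pol2a and 3593 for the interaction. Genes called in all sets and in apices were 36 with no filter and 4 at adjusted p under 0.01.

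Leaving out 1 library at a time gave 10 to 2525 for ld apices, 515 to 922 for pol2a, 2727 to 4155 for ld pol2a against Col0, 3862 to 8442 against ld, 966 to 2215 against pol2a and 494 to 3619 for the interaction. For ld apices the counts were 10 without Col0 1, 18 without Col0 2, 324 without Col0 3, 19 without ld 1, 18 without ld 2 and 2525 without ld 3. For pol2a they were 538 without Col0 1, 515 without Col0 2, 640 without pol2a 1 and 528 without pol2a 2. For ld pol2a against Col0 they were 2816 without ld pol2a 2 and 2727 without ld pol2a 3. Against ld they were 4135 without ld 2, 3862 without ld pol2a 2 and 3955 without ld pol2a 3. Against pol2a they were 1225 without pol2a 2, 1117 without ld pol2a 2 and 966 without ld pol2a 3. For the interaction they were 535 without Col0 1, 631 without Col0 2, 887 without ld 1, 630 without ld 2, 3619 without ld 3, 528 without pol2a 2, 754 without pol2a 3, 494 without ld pol2a 2 and 505 without ld pol2a 3. Seedling counts stayed within 18830 to 18862 for fld, 18472 to 18568 for ld, 12921 to 14029 for ld against fld, 15397 to 15684 for ld and 10575 to 10802 for pol2a in set 2, and 19530 to 19886 for ld in set 3.

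Deviations of 12 of 18 same-number pairs of apex libraries correlated by more than 0.1 (lowest -0.327). Numbers paired all 3 libraries for ld with Col0 (0.271, 0.603 and 0.619) and pol2a with Col0 (0.399, 0.511 and 0.275), not for ld pol2a with Col0 (0.326, -0.319 and 0.421). With the block pol2a apices gave 1469 genes and ld pol2a 5714. In set 2 none (0) of 18 same-number pairs passed 0.1. The missing direction there sets replicate 1 (weights 0.199 in Col0, 0.304 in ld, 0.521 in pol2a and 0.506 in ld pol2a) against replicates 2 and 3 in every genotype. Its absence lowers same-number correlations, so the count cannot show whether numbers pair libraries in set 2. The cause of these correlations was not tested. New spike-in factors and mapping of raw reads were not run. With the depth and the spread of the apex libraries, 56.7% of simulated 2-fold and 93.9% of 4-fold changes were recovered.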

Other observations

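Genes encoded in the mitochondrion lay below the shift in set 1, with medians of -1.24 in fld and -1.01 in ld relative to it, and above it in pol2a of set 2 (0.55). In set 2 their share of the signal overlapped between pol2a (1.32% to 1.99%) and Col0 (1.40% to 1.98%), and ld pol2a (1.07% to 1.13%) lay below every other library of the set. These classes were set beforehand and were not tested as lists. Of 296 ribosomal protein genes, limma called 241 higher and 10 lower relative to the shift in ld pol2a of set 2 (median 0.34), against 5681 and 5507 of all 19444 genes. In ld pol2a apices edgeR called 153 higher and 10 lower (median 0.46), against 2774 and 2033 of 18705. In the apex interaction it called 137 upwards and none (0) downwards (median 0.69), against 959 and 451 of all genes.

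Of 137 long non-coding RNA genes, also not tested as a list, limma called 66 higher and 9 lower relative to the shift in ld of set 1 (median 0.40), against 4846 and 5263 of all 19069 genes. In pol2a of set 2 it called 9 higher and 69 lower of 154 (median -0.33), against 5841 and 5806 of 19444. HEI10 was at 97.2 ± 19.99 in ld of set 1 and 156 ± 25.2 in ld pol2a of set 2 (n = 3).

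The splits of libraries, the test of overlapping counts, of 1 library apart and of fewer reads were written before their results, and the other tests after. Totals were higher in ld, fld and ld pol2a. A few genes taking most of the total is excluded: without the 100 highest genes 0.932 of the log2 difference remained. More reads in the mutant libraries fell short of the rise: read totals matched at most 0.338 of it on the log2 scale. Signal is reads divided by a factor, so this does not test whether depth was fully scaled out. A spike-in factor that differs for a technical reason may also raise totals. Totals were higher in ld in 3 of 3 sets, which either would give, so these cannot be told apart while each library has 1 factor that goes with its genotype.

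MRD1 and the overlapping HEI10 were higher together in ld, pol2a and ld pol2a. Reads of MRD1 counted for HEI10 could give part of this: the gain of HEI10 was 0.0831 to 0.192 of that of MRD1 in sets 1 and 2 and apices, a largest over smallest ratio of 2.31, and 1.01 in set 3. They would not raise HEI10 in fld, where MRD1 stayed near 0 (0.925 ± 0.810, n = 3) and HEI10 went from 8.01 ± 2.05 to 50.8 ± 5.11, 0.98 above the shift (limma, adjusted p = 0.000197), so HEI10 also rose without them. Overlapping reads counted for both genes in set 3 is open: the median log2 ratio of set 3 to set 2 Col0 reads was 0.757 higher in overlapped genes. Of the 792 overlapped genes, 44.8% lay more than 1 above the median of genes without overlap (0.747). Of the 13681 genes without overlap, 7.56% did. A difference between seed stocks at this locus may also do it: of 16 values of the flanking genes MSL4 and MUM4 in 8 comparisons, 3 were called higher relative to the shift, 1 lower (MSL4 in pol2a of set 2, -1.25, limma, adjusted p = 0.000215) and 12 were not called. It cannot be told apart, since each stock is tied to its genotype.

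Few genes were called between ld and Col0 apices. A slope on gene length that differs between libraries could hide more: as a covariate it gave 2811, and 20 permuted slopes gave 10 to 927 (median 62.5). The slopes were taken from the same counts, as deviations from group means, so they take out spread within groups only. Permuting them over all libraries undid that centring, so the permuted counts are no like measure. Whether the slope hides changes is open. That 1 library lies apart, ld 3, may explain part: leaving it out gave 2525, and 1223 with the slope as a covariate as well, so this cannot be told apart from the slope, which is steepest in ld 3. Fewer reads in the ld libraries is excluded, with a mean read total 0.97 of that of Col0.

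Where 3 libraries face 3, 10 splits are too few for a share under 0.05. Every other split also mixes the genotypes, so a large difference between them widens the spread within its parts and lowers its count. A first rank was thus largely fixed beforehand where the genotypes differ strongly, and decides little. The real split ranked 1 of 10 in each seedling comparison (highest other 0, 1 in ld pol2a against pol2a, 5 in set 3), and 1 of 10 in pol2a apices (highest other 1) and in the 3 ld pol2a comparisons of apices (highest other 0). For ld apices it ranked 2 of 10: the split of Col0 1, Col0 3 and ld 3 from the others called 1380 against 181, which points to a structure of the samples. That split parts 1 pair, and the 3 other splits that part 3 pairs, as the real one does, called none (0) by edgeR. The interaction ranked 4 of 100 in set 2 (17130, highest other 18540) and 2 of 100 in apices (1410, highest other 1479). Its regroupings mix genotypes too, so these ranks also decide little. The correlation of ld and fld ranked 48 of 100 (0.615, highest other 0.922). Chance is not excluded by this rank, which decides little, since regroupings that mix Col0 with mutants still carry differences between genotypes. The overlaps ranked 1 of 100 each, with 14954 and 55 genes against a highest other of 0. The other splits called none (0) in ld of sets 1 and 2 by limma, so this rank says nothing of sharing beyond those counts. Independent lists of the same lengths would share 14440 and 51.5 higher genes, against 14949 and 54.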
